A study of Mus musculus with 16 samples.

How the data were processed

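Total RNA from mouse neural stem cells was sequenced in 12 libraries, 6 labelled gRNA and 6 labelled control, and ribosome footprints were sequenced in 4 further libraries, 2 per group. Per the labels' protocols, RNA was purified with the RNeasy Mini kit and made into stranded, ribosomal-RNA-depleted libraries, and footprints came from a ribosome pulldown with LACEseq library preparation by Immagina. Each RNA-seq library carries a batch label, and each of the 2 batches holds 3 gRNA and 3 control libraries.

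Per the submitters' processing notes, RNA-seq reads were handled with Trimmomatic, STAR, SAMtools and HTSeq on GRCm39; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw read counts per Ensembl gene, not normalized, for 57132 genes in each library. The 5 summary lines that HTSeq adds were left out of library sizes and tests. Reads assigned to no gene made up 18.95% to 25.07% of each library in batch 1 and 8.83% to 12.7% in batch 2, ambiguous reads 3.22% to 4.06% and reads without a unique alignment 1.87% to 2.77%. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart here, and genes with near-identical copies, such as histone and ribosomal protein genes, are uncertain as single genes. Symbols were matched to 51880 gene identifiers (90.8%).

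For the footprints, the submitters' processing notes name cutadapt 5.2, UMI-tools 1.1.6 and STAR 2.7.10b on GRCm39; the tool that assigned P-sites is not given in the sources used here. The deposited P-site table has 2859681 entries on 74042 transcripts, each with a footprint length of 26 to 32 nt and the position of the ribosomal P-site from the start and the stop codon. No 2 entries are identical, so footprints at the same position and of the same length count as 1, and the same footprint can stand under several transcripts of a gene. The table names 4 libraries, and 0 of these names match a label. No group could therefore be given to a footprint library: the planned tests of footprints per gene, of translational efficiency and of gene lists in the footprints were not run, and values are given per library. Reading frame was computed over P-sites in the coding sequence (CDS), with 95% Wilson intervals that cover counting error only. They treat entries as independent, so they are too narrow where 1 footprint stands under several transcripts.

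RNA-seq counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10, libraries scaled by TMM, and gRNA compared with control by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The comparison over both batches had batch as a term. Each batch was also tested alone, and the difference of the effect between batches was tested as an interaction. All log2 fold changes are gRNA against control unless another contrast is named, levels are CPM from TMM-scaled library sizes, and intervals are at 95%. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Of 31 lists, 28 had at least 5 tested members.

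Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among genes past the threshold. Where fewer than 5 genes passed, it took the 5 with the smallest p among genes with a mean of at least 50 counts, leaving out predicted genes, pseudogenes and clones and, over both batches, genes whose direction differed between them. It added up to 4 members with the smallest p of each list and 8 markers, among them Sox2, Nes, Olig2, Gfap, Dcx, Tubb3 and Mki67. Of the genes this rule took, 3 are not reported here and were left out of the screen for distant libraries; they remain in the tests, the lists and the counts of alternative values. Alternatives were size factors and the Wald test of DESeq2 1.42.0, other low-count filters, no batch term, a minimum fold of 1.2, limma-voom and leaving out each library. Surrogate variables (sva 3.50.0), library quality weights, leaving out a pair of libraries that stand apart, and a fixed P-site offset were added after seeing the data. Figures and footprint values used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

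The fits were tested on simulated counts with the real means, dispersions and library sizes. Over both batches, with 17704 genes simulated, 45.7% of genes changed 1.5-fold, 57.1% of those changed 2-fold and 91.7% of those changed 4-fold were recovered at an adjusted p under 0.05. The shares were 22.9%, 61.4% and 90% for batch 1 (16988 genes), 12.9%, 52.9% and 81.7% for batch 2 (15647 genes) and 1.4%, 27.1% and 71.7% for the difference between batches (18279 genes). A simulated shift of 0.2 in the DNA replication list gave a camera adjusted p of 7.46e-11, and 0.000614 with an estimated correlation, with 0 of the 27 other lists called. Genes were simulated independently, whereas the estimated correlation of this list in the real counts was 0.811. The simulated list values therefore do not tell how often lists are found or falsely called in the real counts.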

Results

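Mouse neural stem cells were profiled in a series on self-renewing conditions, in which cells labelled gRNA were set against cells labelled control. The series title names the agent as TAPIR. Neither TAPIR nor a target of the guide RNA is explained in the labels, so the level of a targeted gene could not be checked. RNA-seq covered 6 gRNA and 6 control libraries in 2 labelled batches of 3 against 3, and ribosome profiling, which sequences the mRNA fragments covered by ribosomes, covered 4 libraries. The RNA-seq libraries held between 8414028 and 19454390 read counts in genes, with a median of 14918917. None of the 66 pairs of libraries had identical counts. Nothing in the labels says that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

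The batches differed far more than the treatments. A principal component that separated the batches held 85.4% of the variance, and correlations of log2 levels were 0.857 to 0.874 between libraries of different batches and 0.976 to 0.995 within a batch. Within batches, 9 of the 12 libraries correlated best with a library of the other treatment. Control library 6 held 21.6% of the variance within batches and gRNA library 6 held 12.8%, and the other libraries held 4.9% to 9.7% each.

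Over both batches, the transcription factors and filament protein that mark neural stem cells did not pass the test for a difference between gRNA and control libraries. Sox2, which maintains the progenitor state, had a log2 fold change of −0.16 (SE 0.11, 95% interval −0.39 to 0.08, n = 6 per group), and Nes, the intermediate filament of neural progenitors, −0.11 (SE 0.12). The oligodendrocyte lineage factor Olig2 was at −0.16 (SE 0.13) and the proliferation marker Mki67 at −0.06 (SE 0.09). Leaving out 1 library moved these values by over 1.5 times and turned none of them: Sox2 was at −0.074 without control library 6 and Olig2 at −0.024 without control library 2. Nes was at −0.205 without gRNA library 1, −0.043 without gRNA library 2 and −0.019 without control library 2. Mki67 was at −0.106, −0.021, −0.038 and −0.109 without gRNA libraries 1, 2, 4 and 6 and at −0.011 and −0.036 without control libraries 2 and 6. In batch 1, Sox2 was at 160 ± 26.1 CPM in control and 148 ± 24.5 CPM in gRNA libraries (SD, n = 3 each), and in batch 2 at 156.5 ± 31.2 and 136 ± 12.3 CPM. Mki67 was at 753 ± 112 and 713 ± 94.4 CPM in batch 1 and at 692 ± 50.7 and 671 ± 79.5 CPM in batch 2.

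The fixed markers of neurons and astrocytes, Tubb3, Dcx and Gfap, were low or variable. Tubb3, a neuronal tubulin, had a log2 fold change of −0.22 (SE 0.20) and Dcx, a microtubule protein of young neurons, −0.20 (SE 0.61), with Dcx at 2.39 ± 1.02 and 2.87 ± 1.01 CPM in the control and gRNA libraries of batch 1 (SD, n = 3 each). Gfap, the astrocyte filament, was at 0.26 (SE 0.89, interval −1.66 to 2.17). Its spread came from batch 2, where control libraries had 11.2 ± 17.4 CPM and gRNA libraries 13.9 ± 23.3 CPM, against 14.1 ± 1.09 and 16.3 ± 3.31 CPM in batch 1. The direction of Gfap turned without gRNA library 6 (−1.18) and that of Dcx without control library 6 (0.27), and Tubb3 was at −0.127 without control library 3 and −0.055 without control library 6.

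**Figure D1:**
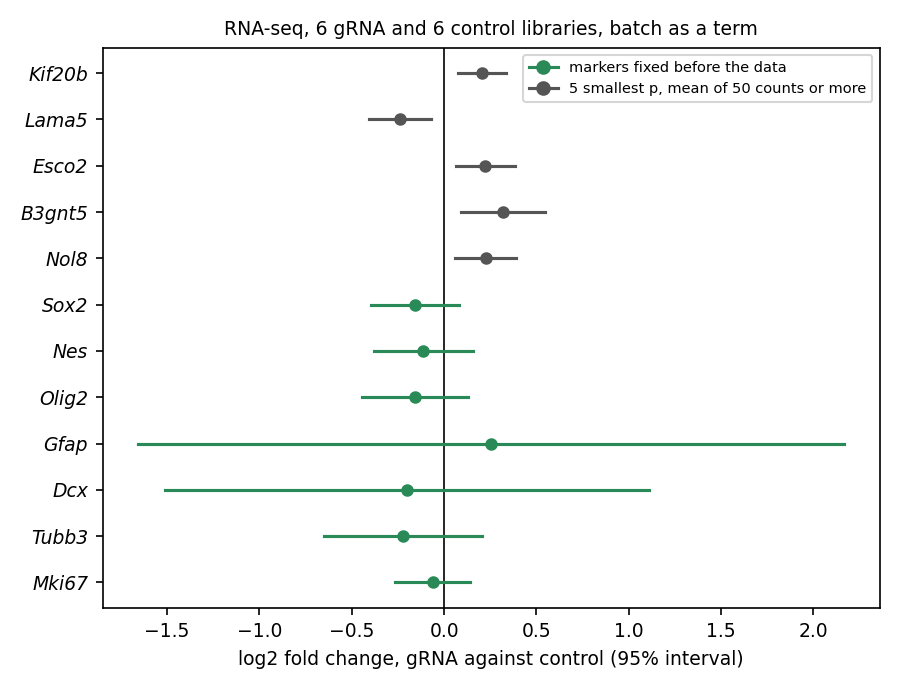
Log2 fold changes of gRNA against control on the horizontal axis for 7 markers fixed before the data were examined and the 5 genes with the smallest p among those with a mean of at least 50 counts and the same direction in each batch (points), with 95% intervals (lines), from 6 gRNA and 6 control RNA-seq libraries with batch as a term. Kif20b lies at 0.20, Lama5 at −0.24 and Sox2 at −0.16, and the widest interval is that of Gfap, from −1.66 to 2.17.

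Among genes with a mean of at least 50 counts and the same direction in each batch, predicted genes and clones left out, the smallest p-values were those of Kif20b, a kinesin of late cell division, at a log2 fold change of 0.20 (SE 0.06), and Lama5, a laminin chain of the basement membrane, at −0.24 (SE 0.08). Of the next 3, Esco2, an acetyltransferase for sister chromatid cohesion, was at 0.22 (SE 0.07), the glycosyltransferase B3gnt5 at 0.32 (SE 0.11) and Nol8, a nucleolar protein, at 0.23 (SE 0.08). Kif20b was at 129 ± 2.92 and 146 ± 10.9 CPM in the control and gRNA libraries of batch 1 and at 92.4 ± 6.46 and 109 ± 4.21 CPM in batch 2 (SD, n = 3 each). The smallest adjusted p in edgeR was 0.9998, so none of these values passed. Of 17704 genes tested, edgeR called 0, with 230 at an unadjusted p under 0.05 where evenly spread p-values would give 885. DESeq2 called 0 (285 at an unadjusted p under 0.05) and limma-voom 0 (232). The 95% interval excluded a change of 2-fold or more for 15786 genes (89.2%) and of 1.5-fold or more for 64.9%, and the biological coefficient of variation was 16.9%. Without a low-count filter edgeR called 1 gene, Fosb, an immediate early transcription factor, lower in gRNA libraries.

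Among the fixed gene lists, 1 lay higher and 5 lay lower as groups in gRNA libraries by camera with a preset correlation. The DNA replication list, enzymes and licensing factors of S phase, had all 32 tested members above 0 with a median log2 fold change of 0.125 (adjusted p = 2.42e-06, and adjusted p = 0.9996 with an estimated correlation), among them the checkpoint mediator Clspn at 0.24 (SE 0.12), or 0.136 without control library 6. The list's median was 0.005 in batch 1 and 0.257 in batch 2. Neural stem and progenitor genes had 23 of 28 members below 0 and a median of −0.12 (adjusted p = 0.00482, and adjusted p = 0.9996 with an estimated correlation), with the transcription factor Sox3 at −0.26 (SE 0.10) and the growth factor receptor Egfr at −0.21 (SE 0.11), or −0.132 without gRNA library 6. The quiescence and BMP list had 18 of 22 below 0 and a median of −0.11 (adjusted p = 0.0206, and adjusted p = 0.9996 with an estimated correlation), with the antiproliferative gene Btg2 at −0.34 (SE 0.17), or −0.145 without control library 6 and −0.0145 in batch 1. Within batches, the medians were −0.083 and −0.144 for the progenitor list and −0.022 and −0.149 for the quiescence list.

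Replication-dependent histones, made in S phase to package new DNA, had 46 of 52 members below 0 and a median of −0.16 (adjusted p = 0.00178, and adjusted p = 0.9996 with an estimated correlation), with Hist1h2be at −0.31 (SE 0.16) and Hist1h3d at −0.35 (SE 0.19), which were −0.174 and −0.218 without control library 6. Cytosolic ribosomal proteins had 77 of 83 below 0 and a median of −0.092 (adjusted p = 0.00482, and adjusted p = 0.9996 with an estimated correlation), with Rps2 at −0.17 (SE 0.16) and Rplp0 at −0.17 (SE 0.16). Without control library 2 these lay at −0.006 and −0.0023, without gRNA library 1 at −0.264 and −0.259, and Rplp0 at −0.11 without gRNA library 2. Nuclear-encoded oxidative phosphorylation genes had 74 of 82 below 0 and a median of −0.074 (adjusted p = 0.00539, and adjusted p = 0.9996 with an estimated correlation), with the complex I subunit Ndufs7 at −0.12 (SE 0.10) and Atp5s at 0.18 (SE 0.10); Ndufs7 was at −0.054 without control library 2 and −0.077 without gRNA library 3. The medians in batches 1 and 2 were −0.142 and −0.209 for histones, −0.122 and −0.048 for ribosomal proteins and −0.084 and −0.052 for oxidative phosphorylation. Each batch median covers only the genes that the filter kept in that batch. Of the 52 histones, 51 were called lower and 1 higher in batch 2 than in batch 1 (median −4.89, log2). Hist1h3d was at 2.7 and 1.76 CPM in the control and gRNA libraries of batch 2, so the histone median there rests partly on low counts. Fry gave an adjusted p = 0.9955 for every list tested, so none of the 6 calls held with either. Over the 31 lists, 0 members passed when adjusted over the list alone and 0 when adjusted over all genes.

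Single libraries moved these list calls: 1 list was called without gRNA library 2 and 1 without control library 2, 3 without gRNA library 4 and 13 without gRNA library 6. Control library 6, in which the DNA replication list lay at −0.697 on the log2 scale against the mean of its batch and the quiescence list at 0.487, also held the astrocyte list at 1.163, Notch response genes at 0.832, interferon-stimulated genes at 0.693, endothelial and mural genes at 0.656, the oligodendrocyte lineage at 0.524, growth factor response genes at −0.527 and ATF4 targets at −0.511. It ended 3 of the calls when left out: the replication list then had a median of 0.018 and an adjusted p of 0.165, the quiescence list −0.011 and 0.651, and the progenitor list −0.058 and 0.0834. Without control library 2, histones had a median of 0.012 (adjusted p = 0.511), ribosomal proteins turned to 0.036 (0.159), oxidative phosphorylation to 0.02 (0.221), and the progenitor and quiescence lists had adjusted p-values of 0.139 and 0.0934. Without gRNA library 2, all calls but that of DNA replication ended, with adjusted p-values of 0.113 for histones, 0.408 for ribosomal proteins, 0.345 for oxidative phosphorylation, 0.113 for progenitor genes and 0.116 for quiescence. The ribosomal protein and oxidative phosphorylation calls also ended without gRNA library 3 (adjusted p = 0.511 and 0.591), gRNA library 4 (0.104 and 0.13) and control library 4 (0.28 and 0.289). The quiescence call also ended without gRNA library 4 (0.104) and gRNA library 5 (0.284). The adjusted p of the DNA replication list without gRNA library 6 was 0.00525, with a median of 0.077. Without gRNA library 1, the medians were −0.267 for histones, −0.187 for ribosomal proteins and −0.156 for oxidative phosphorylation. Without control library 3 they were −0.157 for ribosomal proteins and −0.13 for oxidative phosphorylation.

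**Figure D2:**
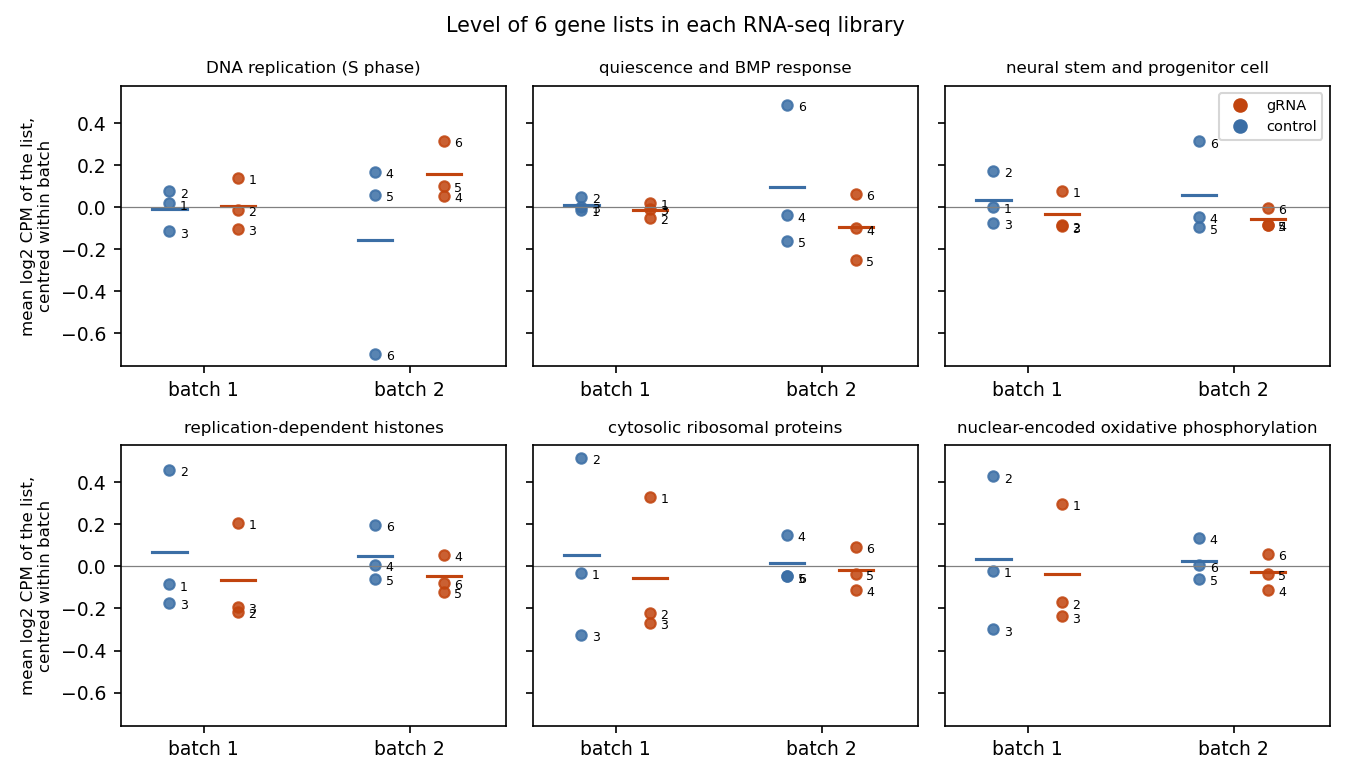
Mean log2 CPM of 6 gene lists in each RNA-seq library, centred within batch (vertical axis), for control (blue) and gRNA (orange) libraries of batch 1 and batch 2; points are libraries with their number in the order of the labels and bars are the means of 3. Control library 6 lies lowest for DNA replication (−0.697) and highest for the quiescence list (0.487).

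The other 22 lists did not pass camera, with medians from −0.187 to 0.011 and a smallest adjusted p of 0.0617. Mitochondrially encoded mRNAs had the lowest median, −0.187, with mt-Co1, a cytochrome oxidase subunit, at −0.20 (SE 0.19). While mt-Co1 was at 166 and 139 CPM in batches 1 and 2, other members of this list lay near the floor. These were mt-Atp6 (0.24 and 0.85 CPM), mt-Co2 (0.52 and 1.79 CPM) and mt-Co3 (0.58 and 1.45 CPM), so the list median rests partly on low counts. Fatty acid synthesis genes had a median of −0.089, with the synthase Fasn at −0.12 (SE 0.10), and cholesterol biosynthesis genes 0.011, with the regulator Srebf2 at −0.085 (SE 0.08). Medians were −0.021 for translation factors, −0.035 for ATF4 targets of the integrated stress response, −0.014 for the unfolded protein response, −0.037 for heat shock and proteasome genes, 0.003 for p53 targets and −0.06 for NRF2 targets. Ddit4, an inhibitor of mTOR signalling, was at −0.31 (SE 0.12), and Creld2, a chaperone of the endoplasmic reticulum, at 0.20 (SE 0.11), and these lay at −0.197 and 0.133 without control library 6. Without control library 2, mt-Co1 was at 4e-04, Fasn at −0.056 and Srebf2 at −0.032. Without gRNA library 2, mt-Co1 was at −0.129 and Fasn at −0.067. Without gRNA library 1, mt-Co1 was at −0.325.

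Interferon-stimulated genes had a median of −0.049, with Ifit2 at 0.20 (SE 0.13), and NF-kB genes −0.003. Immediate early and other growth factor response genes had −0.02, with Fos at −0.51 (SE 0.19) and Egr1 at −0.21 (SE 0.10); Egr1 was at −0.119 without control library 2, and Ifit2 at 0.13 without gRNA library 3 and 0.295 without control library 3. Notch response genes had −0.166, YAP and TAZ targets −0.051, Wnt and Hedgehog targets −0.024, extracellular matrix genes −0.086, glycolysis and hypoxia genes −0.041 and mitosis genes −0.017. Of the Notch targets, Hey2 was at −1.26 (SE 0.74) and turned to 0.18 without control library 6. Markers of cell types other than the stem cell gave medians of −0.034 for neurons, −0.132 for astrocytes, −0.13 for the oligodendrocyte lineage and −0.055 for endothelial and mural cells. Microglia (0.052), ependyma and choroid plexus (0.178) and embryonic stem cell pluripotency (−0.065) had 4 tested members each, under the minimum of 5 for a list test.

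Some of these 22 lists passed camera with the preset correlation in a single batch or without 1 library. In other splits of the libraries, balanced over batches but not by treatment, this test called a median of 10 lists. A pass here therefore does not tell an effect of the gRNA from differences between libraries. The passes without 1 library were not repeated with an estimated correlation. In batch 1, growth factor response genes (median −0.162, adjusted p = 0.0146) and fatty acid synthesis (−0.145, 0.0374) passed. Each had an adjusted p = 0.9693 with an estimated correlation. In batch 2 their medians were 0.101 and −0.008. In batch 2, mitochondrially encoded mRNAs (−0.138, adjusted p = 0.0261), interferon-stimulated genes (−0.131, 0.0455) and the oligodendrocyte lineage (−0.138, 0.0455) passed. Each had an adjusted p = 0.983 with an estimated correlation. In batch 1 their medians were −0.219, 0.052 and 0.025. Each batch median covers only the genes that the filter kept in that batch. All 43 interferon-stimulated genes tested between batches were called lower in batch 2 than in batch 1 (median −4.88, log2). Several mitochondrially encoded mRNAs were near the floor in both batches. Mitochondrially encoded mRNAs passed without gRNA library 1 (median −0.312, adjusted p = 0.000131), gRNA library 6 (−0.244, 0.00558), control library 1 (−0.238, 0.0433), control library 3 (−0.274, 3.2e-05) and control library 5 (−0.232, 0.0297). Without control library 6, growth factor response genes (−0.128, 2.7e-05), ATF4 targets (−0.111, 4.1e-05), cholesterol biosynthesis (−0.07, 8.8e-05) and fatty acid synthesis (−0.094, 0.0048) passed lower. Cholesterol biosynthesis passed higher without control library 4 (0.056, 0.0469). Without gRNA library 6, fatty acid synthesis (−0.137, 0.00356), Notch response (−0.217, 0.0139), heat shock and proteasome (−0.077, 0.0174), astrocyte (−0.221, 0.0325), NRF2 (−0.096, 0.0325) and glycolysis and hypoxia genes (−0.103, 0.0356) passed. Interferon-stimulated genes passed without gRNA library 3 (−0.154, 0.00883), control library 1 (−0.135, 0.0091) and control library 4 (−0.065, 0.0456). YAP and TAZ targets passed without gRNA library 3 (−0.137, 0.0321). Fatty acid synthesis passed without gRNA library 1 (−0.115, 0.0193) and control library 3 (−0.115, 0.00156). Heat shock and proteasome genes passed without gRNA library 1 (−0.098, 0.0375) and astrocyte genes without control library 3 (−0.17, 0.0445).

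**Figure D3:**
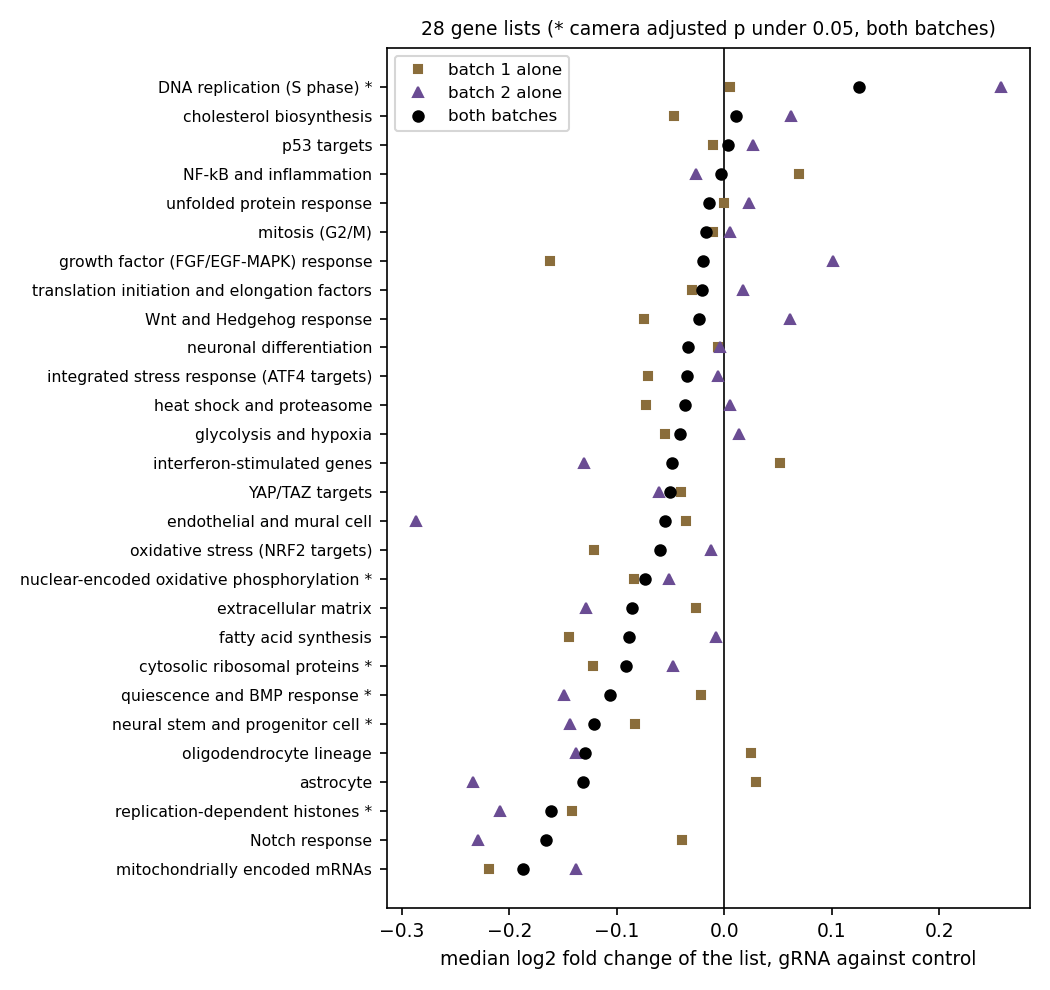
Median log2 fold change of gRNA against control (horizontal axis) for 28 gene lists over both batches (circles) and in batch 1 (squares) and batch 2 (triangles) alone; a star marks a camera adjusted p under 0.05 over both batches with the preset correlation. The DNA replication list lies at 0.005 in batch 1 and at 0.257 in batch 2.

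Within batch 1, the smallest p-values among genes with a mean of at least 50 counts, predicted genes and clones left out, belonged to Tmem158, a membrane protein, at a log2 fold change of −0.38 (SE 0.11), and to Lama5 at −0.37 (SE 0.12), from 454 ± 27.1 CPM in control to 349 ± 40.3 CPM in gRNA libraries (SD, n = 3 each). The zinc finger gene Zfp940 was at 0.45 (SE 0.15), the adhesion molecule Vcam1 at 0.25 (SE 0.09) and the chromatin factor Adnp at −0.47 (SE 0.17). In batch 2, Tmem158 was at 0.23, Zfp940 at −0.11 and Vcam1 at −0.69, against the direction of batch 1, and Lama5 was at −0.088 and Adnp at −0.38. In edgeR 0 of 16988 genes passed (smallest adjusted p = 1), with 147 at an unadjusted p under 0.05; DESeq2 called 0, with 92. The 95% interval excluded a change of 2-fold or more for 82% of genes. Without a low-count filter edgeR called 1 gene, the predicted gene Gm9843, higher in gRNA libraries.

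Within batch 2, Nmi, an interferon-induced protein, had a log2 fold change of 0.55 (SE 0.17, n = 3 per group), Pnmal1 was at 0.69 (SE 0.23) and the zinc finger gene Jazf1 at 0.53 (SE 0.20). Egr1, an immediate early transcription factor, was at −0.24 (SE 0.08). In batch 1 these 4 genes were at 0.0028, 0.072, 0.10 and −0.17. In edgeR 0 of 15647 genes passed (smallest adjusted p = 0.9976), with 116 at an unadjusted p under 0.05; DESeq2 called 0, with 167. The 95% interval excluded a change of 2-fold or more for 78.4% of genes.

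Xaf1, Perp and Hist1h2bm, among the 5 genes with the smallest p-values for a difference of the gRNA effect between batches at a mean of at least 50 counts, lay near 0 in batch 2. Xaf1, an interferon-induced apoptosis factor, was at 22 ± 6.69 and 27.9 ± 5.12 CPM in the control and gRNA libraries of batch 1 and at 0.421 ± 0.203 and 0.106 ± 0.0424 CPM in batch 2 (SD, n = 3 each). Perp, a p53 target of cell adhesion, was at 11.3 ± 0.348 and 12.5 ± 0.486 CPM in batch 1, and in batch 2 at 0.0912 ± 0.0802 CPM in control and at 0 in all gRNA libraries. Gramd1c had a difference of −0.86 (SE 0.31, batch 2 minus batch 1, log2), the tight junction gene Tjp3 −1.18 (SE 0.44) and the histone gene Hist1h2bm, at 34.2 ± 8.27 and 30.8 ± 3.1 CPM in batch 1 and at 0.277 ± 0.118 and 0.587 ± 0.178 CPM in batch 2, 1.26 (SE 0.47). In edgeR 0 of 18279 genes passed (smallest adjusted p = 0.9999), with 236 at an unadjusted p under 0.05; DESeq2 called 0, with 261. Without a low-count filter edgeR called 42, 7 higher and 35 lower. By camera, DNA replication (adjusted p = 3.07e-06, up), interferon-stimulated genes (0.00887, down) and cholesterol biosynthesis (0.0185, up) differed between batches, and with an estimated correlation every list had an adjusted p = 0.9917.

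Ribosome footprints lay mainly in coding sequence in each of the 4 libraries of the P-site table, which are numbered 1 to 4 here because their names match no label. Of footprints on coding transcripts, 87.7% (95% interval 87.6 to 87.7), 88.9% (88.7 to 89), 86.3% (86.1 to 86.4) and 86.2% (86 to 86.5) were in the CDS. The 5′ untranslated region held 4.42% to 7.48% and the 3′ untranslated region 6.24% to 7.01%. Transcripts without a CDS took 28.1% to 35.7% of all entries. The libraries had 2174905, 250755, 331338 and 102683 entries, so library 1 alone gave 76.1% of the table.

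Translating ribosomes move codon by codon, and the share of CDS P-sites in frame 0, the frame of the start codon, was 53.7% (interval 53.6 to 53.8), 44.9% (44.7 to 45.2), 48.7% (48.5 to 49) and 41.4% (40.9 to 41.8) in libraries 1 to 4. In library 4, frame 1 held 38.9% against 16.1%, 24.5% and 20.3% in libraries 1 to 3. With an offset of 13 nt for every footprint length, frame 1 held 18.15% in library 4 and 11%, 16.7% and 13.4% in libraries 1 to 3, and in library 4 frame 2 held 40.2%, against 19.7% with the assigned offsets, and frame 0 41.7%. P-sites on the first nucleotide of the start codon numbered 5237, 542, 637 and 171. Over all positions of the start codon, P-sites were 1.97, 1.92, 1.78 and 1.72 times the mean per codon over codons 11 to 100. No gRNA and control libraries could be told apart in this table, so no comparison was made, and 2 libraries against 2 could not have given an exact permutation p below 0.33.

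**Figure D4:**
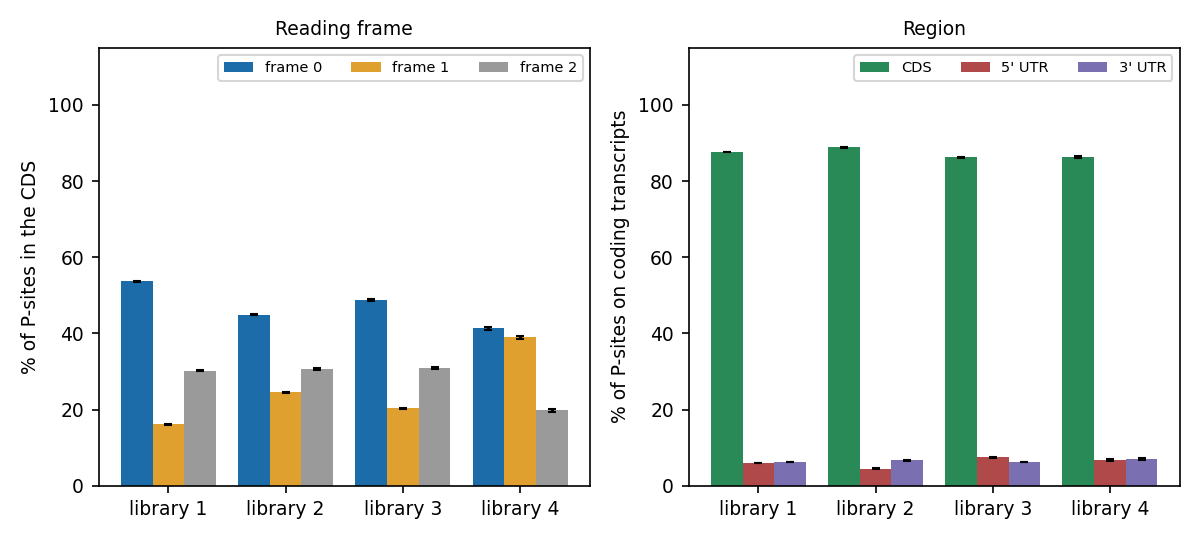
Percent of CDS P-sites in each reading frame (left) and percent of P-sites on coding transcripts in the CDS and the untranslated regions (right) in 4 ribosome profiling libraries. Bars are single libraries and error bars are 95% Wilson intervals, which cover only the counting error of entries taken as independent. Frame 0 ranges from 41.4% in library 4 to 53.7% in library 1.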

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

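The screen for distant libraries was set before the data were examined, and the tests of the DNA replication list without control library 6, in batch 1 alone and in other splits were chosen after the result was seen.

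Levels of reported genes and called lists were centred within batch on the log2 scale. Then 178 groups of 6 libraries were screened for a library far from the other 5. Chance gives about 1 in 20 groups for independent values of equal spread. The groups here share the same libraries and hold some genes picked for small p-values, so that rate is no measure of excess. In this screen 25 values stood apart. Control library 6 held 17 of them and gRNA library 6 held 4. In control library 6, Gfap (3.39) and Vwf (2.27), markers of astrocytes and endothelium, Dcx (2.33), the Notch target Hey2 (3.08), Vcam1 (1.59), Btg2 (0.89), Tjp3 (0.76), the myelin enzyme Cnp (0.73), the Hedgehog receptor Ptch1 (0.65), the kinase Eef2k (0.6) and Dtx4 (0.48) lay above the other control libraries. Ccl2, a chemokine (−3.31), Elavl4, a neuronal RNA-binding protein (−1.1), Tmem158 (−0.98) and Clspn (−0.7) lay below them. The same library held the lowest mean of the DNA replication list (−0.697) and the highest of the quiescence list (0.487). In gRNA library 6, Flt1, a VEGF receptor (1.93), the coagulation factor receptor F3 (0.66), B3gnt5 (0.56) and Adnp (0.04) stood apart from the other gRNA libraries. Each library was set against its own group only. Gfap was also variable in the gRNA libraries of batch 2 (13.9 ± 23.3 CPM), and the astrocyte list lay at 0.482 in gRNA library 6. Dcx was near the floor in the control libraries of batch 2 (0.29 ± 0.50 CPM). Other values that stood apart were Egr1 in gRNA library 1 (0.07), Sesn2 in control library 1 (−0.16), and the YAP targets Amotl2 (0.52) and Ajuba (0.12) in gRNA library 3.

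Camera gave a difference of the gRNA effect between batches for DNA replication (adjusted p = 3.07e-06, medians 0.005 in batch 1 and 0.257 in batch 2), interferon-stimulated genes (0.00887, medians 0.052 and −0.131) and cholesterol biosynthesis (0.0185, medians −0.047 and 0.062). With an estimated correlation all 3 had an adjusted p of 0.9917. Each batch median covers only the genes that the filter kept in that batch, so the 2 medians of a list can cover different genes. Interferon-stimulated genes were all called lower in batch 2 than in batch 1 (43 of 43, median −4.88, log2). Within batch 2, control library 6 held this list at 0.693 against the batch mean.

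The higher DNA replication list in gRNA libraries may be carried by control library 6, since its median fell from 0.125 to 0.018 without that library. Chance cannot be excluded either: 45 of 100 batch-balanced splits, the real one included, gave a median as far from 0, with the real value at 0.125 and the highest other at 0.267. An effect of the gRNA of the same size in each batch would need a like median in batch 1, where it was 0.005. It stays open because the difference between batches did not hold with an estimated correlation (adjusted p = 0.9917). What set control library 6 apart, in the cells or in its preparation, was not tested.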

How the results depend on the processing

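Library quality weights, surrogate variables, leaving out gRNA library 6 and control library 6 together, and the fixed P-site offset were chosen after seeing the data. Of 1759 alternative values for 87 gene fold changes, 1742 kept their direction and side of the threshold and 17, in 8 genes that were not called, reversed. Leaving out 1 library turned 60 of the 87 or moved them by over 1.5 times. Leaving out each library gave 0 called genes in all 4 comparisons. Without a low-count filter, edgeR called 1 gene over both batches (Fosb), 1 in batch 1, 0 in batch 2 and 42 for the difference between batches. The called lists numbered 0 with an estimated correlation, 0 with fry, 4 in batch 1, 9 in batch 2, 13 without the pair of libraries 6 and 1 to 13 when each library was left out. The frame 0 share over all footprints, 52%, became 52.29% without the CDS ends and 51.57% with an offset of 13 nt for every length. The cause was not tested.

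Reversed values were, for Gfap, −0.080 with voom and −0.025 without the pair. For Dcx they were 0.11 without a batch term, 0.030 with voom, 0.195 with quality weights, 0.27 without the pair and 0.24 with surrogate variables. Tubb3 gave 0.0017 with surrogate variables, and Hey2 0.12 without the pair and 0.083 with surrogate variables. Leaving out each library gave ranges of −1.18 to 1.30 for Gfap, −0.59 to 0.27 for Dcx, −0.14 to 0.71 for Oas2, −1.50 to 0.18 for Hey2, −0.32 to 4e-04 for mt-Co1, −0.12 to 1.13 for Flt1 and −0.37 to 0.14 for Klf4. The cause was not tested.

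No paired analysis was possible because the footprint library names match no label and the RNA-seq labels carry no replicate numbers. All alternatives for footprints per gene, translational efficiency and footprint gene lists, and the choice of transcript, were not run. Library 4 of the footprints had the fewest entries, 102683.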

Other observations

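The test of other splits for the batch difference and the tests on RNAs without a poly(A) tail and on replication-independent histones were set before their results were seen; the comparison of batches and every other test in this part were chosen after the data were seen.

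Interferon-stimulated genes and p53 targets lay lower in batch 2 than in batch 1. All 43 interferon-stimulated genes tested were called lower in batch 2 (camera adjusted p = 2.47e-18, and adjusted p = 0.124 with an estimated correlation), for example Oasl2 from 229 ± 30.4 to 0.367 ± 0.289 CPM (SD, n = 6 each). Of 28 p53 targets, 22 were called lower and 2 higher (camera adjusted p = 4e-05, and adjusted p = 0.352 with an estimated correlation), with Zmat3 from 385 ± 26.6 to 142.5 ± 19.9 CPM. Of 28 neural stem and progenitor genes, 19 were called lower and 2 higher (camera adjusted p = 0.0149, and adjusted p = 0.726 with an estimated correlation), with Emx2, a forebrain factor, from 60.7 ± 2.44 to 21.4 ± 1.72 CPM, while Sox2 (154.5 ± 23.5 and 146 ± 24 CPM), Nes (602 ± 138 and 555 ± 31.5 CPM) and the proliferation marker Mki67 (736 ± 95.2 and 680 ± 60.4 CPM) were not called. Of 21 genes of neuronal differentiation, 14 were called lower and 4 higher (camera adjusted p = 0.0344, and adjusted p = 0.124 with an estimated correlation), and Dcx fell from 2.64 ± 0.949 to 0.155 ± 0.352 CPM while Tubb3 rose from 3.31 ± 0.866 to 17.1 ± 4.81 CPM. Among the genes called higher in batch 2, Hoxa5 went from 0.0167 ± 0.0408 to 49.8 ± 2.48 CPM, Hoxa10 from 0.0776 ± 0.0731 to 34.7 ± 3.87 CPM and Shox2 from 0.0267 ± 0.0432 to 27.95 ± 6.19 CPM.

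In all, edgeR called 10041 of 16557 genes between batches, 4662 higher and 5263 lower in batch 2 and 116 without a fold because a batch was at 0, and DESeq2 called 14732. Random division of the libraries is an unlikely source of this count. Only 1 of 100 splits of 6 against 6, the real one, gave as many (real 10041, highest other 0). Every other split mixed the batches, so the splits tie the count to the batch label and no further. They cannot tell whether the libraries of a batch are independent samples. The Y-linked gene Ddx3y had 30.1, 30.3 and 67.7 CPM in gRNA libraries 1 to 3 and 30.5, 23.8 and 65.3 CPM in control libraries 1 to 3, and 0 counts in all 6 libraries of batch 2. Xist was at 768 to 1100 CPM in batch 1 and 1220 to 1480 CPM in batch 2. Library preparation alone is argued against for the Y-linked genes: Eif2s3y and Kdm5d, like Ddx3y, had 0 counts in all 6 libraries of batch 2. In batch 1 they had 158 to 761 and 152 to 845 counts. The comparison over both batches thus joined cells that differed in these genes. For other genes, batch is confounded with any difference of culture or library preparation.

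Replication-dependent histone mRNAs, which lack a poly(A) tail, were called lower in batch 2 for 51 of 52 genes and higher for 1 (camera adjusted p = 7.72e-21, and adjusted p = 0.124 with an estimated correlation), with Hist1h1a from 76.2 ± 21.4 to 0.928 ± 0.251 CPM. Fewer cells in S phase are argued against by the DNA replication list, whose median was 0.09, and lower expression of all histone genes by 8 replication-independent histones with a median of 0.08 (−0.03 to 0.66). Capture of polyadenylated RNA in batch 2 is a candidate explanation that stays open: 10 other RNAs without a poly(A) tail had a median of −1.96, 7 of them called lower, with Scarna2 at −6.3 and Rny1, called higher, at 1.2. Apart from Scarna2 (20.8 CPM), these RNAs were low already in batch 1, from 0.524 CPM for Rny1 to 3.89 CPM for Snord17, so they weigh little. The labels name the same total RNA kit for both batches.

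Small p-values numbered 230 in the comparison of gRNA with control, where evenly spread p-values would give 885. Chance cannot be excluded for a count this low, since 15 of 100 batch-balanced splits, the real one included, gave as few. A test that is conservative on independent counts is argued against, since 4.78% of unchanged simulated genes had a p under 0.05. The simulation held no library structure beyond batch, so it cannot tell whether such structure made the test conservative here. Differences between libraries within a batch that cross the treatment may account for the low count. In the other batch-balanced splits the median was 718 genes and the highest 3313. By the count of closest libraries, pairs of gRNA and control libraries from shared cultures cannot be told apart from chance. Of the 400 ways to give the treatment within batches, a share of 0.28 had as many as 9 libraries closest to the other treatment. That count cannot speak to single pairs. Libraries gRNA 3 and control 3 correlated best with each other (0.9946). Their Ddx3y (67.7 and 65.3 CPM) and Kdm5d (46.9 and 44.5 CPM) lay above the other libraries of batch 1 (23.8 to 30.5 and 18.7 to 23.6 CPM). Whether they shared cells was not tested.

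Chance cannot be excluded for the count of lists called between gRNA and control, since 84 of 100 splits gave as many (real 6, median other 10, highest other 19). A count of 0 genes is met by each split, so the 100 of 100 splits over both batches (real 0, highest other 1) and for the difference between batches (real 0, highest other 425) decide nothing. The 10 splits of batch 1 are too few for a share under 0.05 (real 0, highest other 1077), as are the 10 of batch 2 (real 0, highest other 0). The splits with 1077 and 425 genes point to a structure of the samples: the former set gRNA 1, control 1 and control 2 against the rest of batch 1, and these are the 3 libraries of batch 1 with the fewest gene counts (10515276, 14301905 and 8414028, against 17143345 to 19454390), so that structure and depth lie together.

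In the P-site table, the assigned offset was 13 or 14 nt and differed between libraries at the same footprint length. With 13 nt throughout, frame 1 of library 4 went from 38.9% to 18.15%, and the frame 0 gap between libraries 1 and 4 from 12.4 to 11.5 percentage points, or 9.74 with the length mix of library 1.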
